A study of Mus musculus with 6 samples.

How the data were processed

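Single-cell RNA-seq libraries were made from hearts of C57BL/6 mice aged 3 to 6 months. Hearts were digested with collagenase II on a Langendorff perfusion system, cardiac myocytes were removed, and EGFP-positive cells were sorted and loaded on the 10x Genomics Chromium 3′ system. Libraries were read on a NovaSeq6000 with 75-bp paired ends. All mice carried Wt1CreERT2 and the Rosa26mTmG reporter, which switches from membrane Tomato to membrane GFP in cells in which Cre has acted and in their descendants. The control group held 3 libraries, and the Dsp_het group held 3 libraries from mice that also carried 1 conditional allele of Dsp (DspW/F). The labels number the samples within each group and do not say whether each came from 1 animal, so the p-values measure the spread between these samples.

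The deposited matrix holds raw UMI counts for 31055 genes and 18283 barcodes, and the authors' barcode table gives the total UMI counts of each barcode. The column sums of the matrix equalled those totals for all 18283 barcodes, with no tolerance. Other deposited columns hold the number of genes with a count per barcode, the barcodes and the gene symbols, the last 2 of which are GFP and Tomato. The submitters' notes name the GRCm38 genome and Seurat. The aligner, the counting program and the Seurat version are not given in the sources used here. The suffix of each barcode, 1 to 6, was matched to the sample number in each sample's description, and no suffix was left unmatched.

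Library totals ranged from 7573157 to 17083660 UMIs. A barcode was kept with at least 500 UMIs, at least 200 genes and at most 20% of UMIs from mitochondrially encoded genes, which left 16338 barcodes. Scrublet, run per library in scanpy, called 35 of these (0.214%) as doublets, a share so low that doublet removal has not worked. The 35 were left out, so 16303 barcodes were kept, and an alternative left out the 387 highest doublet scores. Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes, 30 principal components and 15 nearest neighbours were computed, and Leiden clustering at resolution 1.0 with seed 0 gave 21 clusters. No integration between libraries was applied.

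Clusters were named from marker lists fixed before the data were examined. The score of a class was the mean, over its markers, of the cluster's CPM relative to the cluster with the highest CPM, using markers held by at least 10% of the cells of some cluster. A cluster took the class with at least 3 markers among its 10 leading genes, ranked by CPM plus a pseudocount of 20 against all other cells, and otherwise the class with the highest score. A name also needed at least 3 markers at a relative level of at least 0.25, and clusters of low depth with no marker among the leading genes stayed unnamed. This scoring rule, unlike the markers, was changed after the clusters had been seen. Barcodes found in several libraries were assigned an owner, the library with the most UMIs of that barcode, if it held at least 0.5 of them. The other occurrences of a barcode with an owner are called copies here, and 3 barcodes had no owner and count as neither.

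Counts were summed per library over all kept cells and within each class that held at least 20 cells in a library. Cardiomyocyte-like cells were not tested, since only 1 Dsp_het library held enough of them. Sums were fitted with edgeR (4.0.16) by quasi-likelihood after TMM normalization and filterByExpr with a minimum count of 10. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Differences of the genotype effect between the 3 largest classes were tested as a class by genotype interaction with library as a block. DESeq2 (1.42.0) served as another tool. Values called normalized CPM are CPM of the library sum after TMM.

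Fixed gene lists, 38 in all, were tested with camera of limma (3.58.1) on voom values, with a preset correlation of 0.01 between genes. Each list needed at least 5 testable members, and p-values were adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Shares of cells and single values were compared by a two-sided exact permutation test, which with 3 against 3 libraries cannot go below p = 0.1. Intervals for shares are 95% Clopper-Pearson intervals. They cover counting error only.

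The genes named in each comparison were set by rule. They are the 12 largest changes in each direction among genes with an adjusted p under 0.05, separated groups and a mean of at least 10 CPM, and up to 4 members per list that passed. Where fewer than 10 genes passed, the 5 smallest p-values in each direction were added and are said to miss the threshold. Dsp, Wt1, Tgfb1, Fgf1, Fgf2, Pdgfra, Col1a1, Postn, Acta2, Pparg and Cdh1 were always included where testable. Cdh1 was too low to be tested in any comparison. Mitochondrial and ribosomal protein genes and genes with clone names were named only as list members, and sex-linked genes were not counted. Gene positions are from GENCODE M21 for GRCm38.

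The comparisons, tests, gene lists, the rule for which genes to name, and most alternatives were chosen before the data were examined. Those alternatives were DESeq2 size factors, no filter on low counts, all deposited barcodes, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial), doublet calls kept, equal numbers of cells per library, Leiden resolution 0.5, each library left out in turn, DESeq2, a block for the replicate number, sex as a covariate, and edgeR on cell counts for the shares. Added after seeing the data were 1 library per barcode, which leaves out all copies and the 3 barcodes with no owner, the same with at least 10 cells per library, and the removal of the highest doublet scores. The sex of each library was read from Xist, with more than 100 CPM taken as female.

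The tests were checked on simulated data with the depths and the spread of these libraries. In sums over all cells, edgeR recovered 59% of genes changed 2-fold and 92% of those changed 4-fold, with 7.36% of its calls false. DESeq2 recovered 70% and 92%, with 17.3% of its calls false. The recovered share of 2-fold changes was 45% in epicardial-like, 62% in fibroblast-like, 82% in endothelial-like, 74% in pericyte-like, 40% in macrophage-like and 16% in cycling cells. For the interaction of epicardial-like and endothelial-like cells it was 27%, with 11.4% of calls false. Simulated genes were independent of each other, so this check says nothing about the correlation that camera assumes. Other tools were R 4.3.3, Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.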

Results

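The data are UMI counts of single EGFP-positive non-myocytes from mouse hearts, 3 control libraries and 3 Dsp_het libraries. Wt1 is a transcription factor of the epicardium, the mesothelial sheet around the heart, so EGFP marks cells in which the Wt1-driven Cre was active and their descendants. Dsp encodes desmoplakin, which ties intermediate filaments to desmosomes, and the series concerns a mouse model of arrhythmogenic cardiomyopathy with 1 Dsp allele lost in this lineage. The control libraries held 3268, 2252 and 3673 barcodes with 11098436, 7573157 and 17083660 UMIs. The Dsp_het libraries held 3641, 3129 and 2320 barcodes with 14121977, 10044075 and 10039589 UMIs. After filtering, 16303 barcodes were kept, with a median per library between 2812 and 4678.5 UMIs. Of the 2320 barcodes of Dsp_het library 3, the filter left out 822, more than in any other library. Xist, the RNA that silences 1 X chromosome in females, reached 492 CPM in control library 3 and 596.3 CPM in Dsp_het library 2, so each group held 1 female and 2 male libraries.

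Of 13183 distinct barcodes, 1689 occurred in several libraries and 530 in all 6. Of the 1689, 1686 had an owner, a library with at least 0.5 of their UMIs, and 3 had none. The occurrences of these 1686 barcodes outside the owner, called copies here, made up 5092 of the 18283 barcodes (27.9%) and 3652 of those kept. Copies held a median of 589 UMIs, 4.97% of those of their owner, against 11020 for owners and 3656.5 for barcodes found in 1 library. They made up between 17.3% and 25.5% of the barcodes of the control libraries and of Dsp_het library 1, but 41.7% in Dsp_het library 2 and 48.9% in Dsp_het library 3. Over all kept cells, copies carried 4.25% of UMIs, so they weigh on counts of cells more than on sums over all cells. Their part of the UMIs was larger in several classes, given below. In the 4 male libraries, Xist was 509.77 CPM in copies whose owner lay in a female library (333 UMIs) and 0.038 CPM in barcodes found in 1 library (1 UMI).

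**Figure D1:**
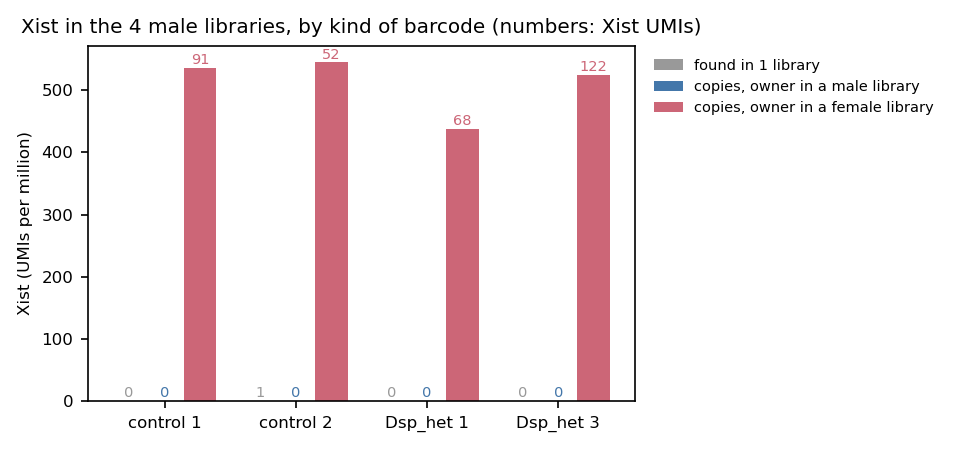
Xist CPM (vertical axis) in the 4 male libraries (horizontal axis), by kind of barcode; the numbers above the bars are Xist UMIs. Xist is present in copies whose owner lies in a female library and almost absent from all other barcodes.

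The kept cells fell into 21 clusters, named from marker genes. Endothelial-like cells were the largest class, 10160 cells (62.3%) in 8 clusters. Of these clusters, 1 was led by the arterial genes Hey1, Gja4 and Sema3g and 1 by the venous genes Vwf and Nr2f2. Others were led by the capillary genes Car4 and Rgcc or by the interferon-induced genes Ifit1 and Isg15, and 1 more held the stress genes Hspa1a and Egr1 among its leading genes. Pooled over libraries, the largest endothelial-like cluster was the arterial one in control (1076 cells) and the venous one in Dsp_het (949 cells). Single libraries did not share this order. The cluster led by Car4 and Rgcc exceeded the arterial one in control libraries 1 (397 against 370) and 3 (494 against 465), but not 2 (162 against 241). It exceeded the venous one in Dsp_het libraries 1 (392 against 389) and 2 (433 against 331), but not 3 (106 against 229). Fibroblast-like cells (2119, 12.998%) expressed Gsn, Lum and Dpep1, and epicardial-like cells (1571, 9.64%) expressed the mesothelial genes Upk3b, Msln and Krt19. Smaller classes were macrophage-like (629, 3.86%; C1qa, Lyz2), pericyte-like (391, 2.40%; Rgs5, Vtn, Kcnj8), cycling (226, 1.39%; Top2a, Mki67) and cardiomyocyte-like cells (159, 0.975%; Myl2, Tnni3). Another 1038 cells (6.37%) stayed unnamed. Copies were 4.94% of endothelial-like cells but 61.7% of epicardial-like, 42.8% of fibroblast-like, 67.6% of macrophage-like and 38.9% of pericyte-like cells. Of the UMIs, copies carried 0.988% in endothelial-like, 6.11% in fibroblast-like, 8.50% in pericyte-like, 11.2% in epicardial-like, 12.5% in cycling and 12.7% in macrophage-like cells. Single libraries differed. With 1 library per barcode, 338530 of 494710 epicardial-like UMIs remained in control library 1, and 1579500 of 1652100 in Dsp_het library 3. For pericyte-like cells it was 48716 of 84532 in Dsp_het library 1 and 994730 of 1026000 in control library 3. The epicardial-like class joined a deep cluster of 517 cells with a median of 10598 UMIs and no copies to a shallow cluster of 1054 cells with a median of 722 UMIs, 92.0% of them copies.

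**Figure D2:**
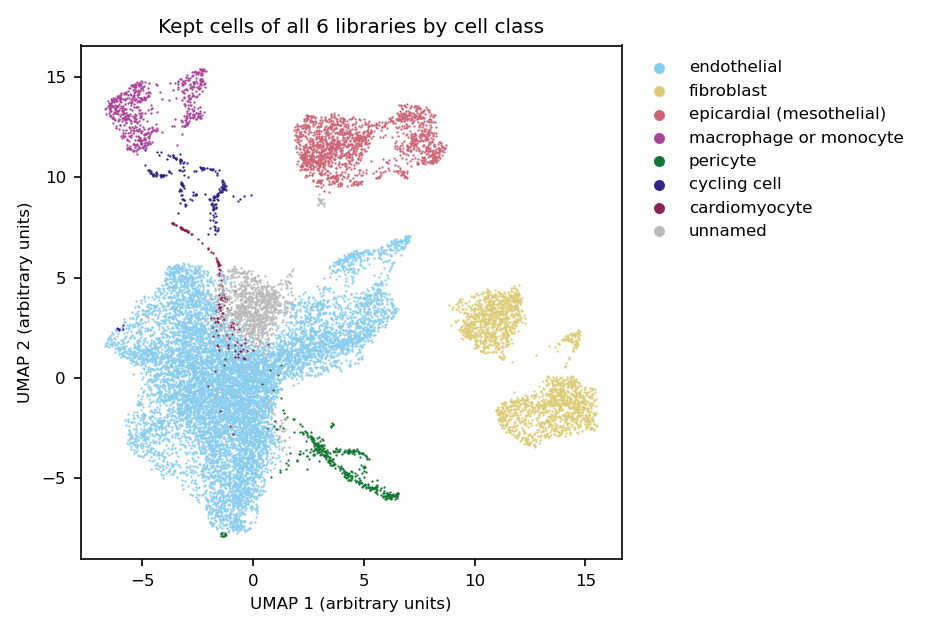
UMAP of the kept cells in the classes described here, 1 point per cell, coloured by class; the 2 axes are the UMAP coordinates and have no unit. Endothelial-like cells, 62.3% of the 16303 kept cells, fill most of the plot, and the epicardial-like and fibroblast-like cells lie apart from them.

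The reporter and Wt1 were measured in each class to show which cells carried the lineage mark. GFP was highest in endothelial-like cells, at 3373 ± 169 CPM in control and 4060 ± 217 CPM in Dsp_het (mean ± SD, n = 3 each; exact permutation p = 0.1). In epicardial-like cells it was 906 ± 112 CPM against 1246 ± 235 CPM, in fibroblast-like cells 789 ± 47.4 against 846 ± 128 CPM, and in macrophage-like cells 156 ± 85.5 against 279 ± 153 CPM. Tomato, the reporter before recombination, was low over all cells, at 10.8 ± 4.79 CPM in control and 8.49 ± 8.97 CPM in Dsp_het. Wt1 (chromosome 2, 105126529 to 105173616, plus strand) was 252 ± 54.9 CPM in control and 276 ± 16.7 CPM in Dsp_het epicardial-like cells, and 27.2 ± 4.98 against 27.1 ± 3.13 CPM in endothelial-like cells. Over all cells Wt1 was 36.9 ± 4.54 CPM in control and 60.8 ± 9.28 CPM in Dsp_het, with the 2 groups separated, at the smallest exact permutation p that 3 against 3 libraries allow (0.1). With edgeR the log2 fold change was 0.71 (SE 0.15, adjusted p = 0.106; 0.00451 to 0.369 over the alternatives), which misses the threshold. The adjusted p was 0.0317 without Dsp_het library 2 and 0.00451 with DESeq2.

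The targeted gene, Dsp (chromosome 13, 38151294 to 38198577, plus strand, protein coding), gave few UMIs. In kept barcodes the control libraries held 15, 18 and 37 Dsp UMIs and the Dsp_het libraries 18, 15 and 34. Kept barcodes held 137 of the 234 Dsp UMIs of all deposited barcodes, against 175740 of 177192 for GFP. Its level over all cells was 2.10 ± 0.616 CPM in control and 2.20 ± 1.35 CPM in Dsp_het (mean ± SD, n = 3 each; exact permutation p = 0.9). In epicardial-like cells, which had the highest level, Dsp was 16.4 ± 6.32 CPM in control and 8.67 ± 1.95 CPM in Dsp_het (exact permutation p = 0.2), from 5, 9 and 19 against 15, 8 and 18 UMIs. The edgeR log2 fold change there was -0.86 (SE 0.36) with an unadjusted p of 0.0313 that did not survive adjustment (adjusted p = 1). Over 17 alternatives, with a lowest adjusted p of 0.971, it stayed between -1.07 and -0.69. Over all cells it was 0.02 (SE 0.46), with -0.56 without Dsp_het library 3, -0.22 without control library 1 and 0.29 without Dsp_het library 1. Epicardial-like cells held 74 of the 137 Dsp UMIs of kept barcodes, and their share of cells was higher in Dsp_het. The value over all cells therefore also carries the mix of cells. A 3′ tag does not show whether an allele was recombined, and no change of Dsp passed at this depth.

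The share of each class among the sorted EGFP-positive cells was compared to ask whether loss of 1 Dsp allele goes with another mix of cells. Epicardial-like cells made up 7.71 ± 0.377% of the kept cells in control and 11.997 ± 1.516% in Dsp_het (mean ± SD, n = 3 each), a log2 ratio of 0.64. Fibroblast-like cells, the main source of collagen in the heart, made up 8.90 ± 1.28% against 16.2 ± 4.21%, a log2 ratio of 0.86. Endothelial-like cells, which line the vessels, were 67.4 ± 3.61% in control and 56.7 ± 2.66% in Dsp_het, a log2 ratio of -0.25. In each of these 3 classes all 3 libraries of a group lay on 1 side of the other group. The exact permutation p was 0.1 for each, the smallest that 3 against 3 libraries allow, and 0.233 after adjustment over 7 classes. EdgeR on the numbers of cells, copies included, gave an adjusted p of 0.00842 for all 3 classes, whose shares depend on each other. It was not run with 1 library per barcode. Pericyte-like cells (3.05 ± 1.18% against 1.97 ± 1.08%, exact p = 0.2), macrophage-like cells (3.57 ± 0.526% against 4.47 ± 1.61%, exact p = 0.5), cardiomyocyte-like cells (1.33 ± 0.893% against 0.638 ± 0.456%, exact p = 0.4) and cycling cells (1.38 ± 0.0899% against 1.53 ± 0.498%, exact p = 0.8) did not separate the groups. Cycling cells had a log2 ratio of -0.13 without Dsp_het library 3, and the groups separated for macrophage-like cells without Dsp_het library 1 and for cardiomyocyte-like cells without control library 1 (exact p = 0.1 for both).

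Copies took part in these shares, so the same shares were computed with 1 library per barcode, a choice added after the data had been seen. Epicardial-like cells were then 2.75 ± 0.655% in control and 7.10 ± 2.32% in Dsp_het, a log2 ratio of 1.37, with libraries at 2.01%, 2.97% and 3.26% against 8.06%, 4.46% and 8.80%. Fibroblast-like cells were 5.56 ± 0.673% against 12.1 ± 7.90%, with libraries at 4.79%, 6.06% and 5.81% against 21.1%, 6.60% and 8.51%, so Dsp_het library 1 gave most of the difference. Endothelial-like cells were 79.7 ± 5.39% against 73.6 ± 8.13% and the groups overlapped (exact permutation p = 0.4). Macrophage-like and cycling cells changed direction, to log2 ratios of -0.43 and -0.22. With all kept barcodes, the exact p was 0.2 for fibroblast-like cells without control library 2 and for endothelial-like cells without Dsp_het library 3, although the groups stayed separated in both. The stricter cell filter also ended the separation of endothelial-like cells (log2 ratio -0.12, exact p = 0.5). Under that filter cells were clustered and named anew. Cardiomyocyte-like cells then made up 7.23 ± 4.61% in control and 3.76 ± 2.86% in Dsp_het, while the main classes held only 159 such cells in all. Shares under that filter therefore also carry a change of naming, whose part was not tested. A cluster of 73 fibroblast-like cells led by Ccl11 and Igfbp3 came almost wholly from Dsp_het library 1, which gave 63 of them.

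**Figure D3:**
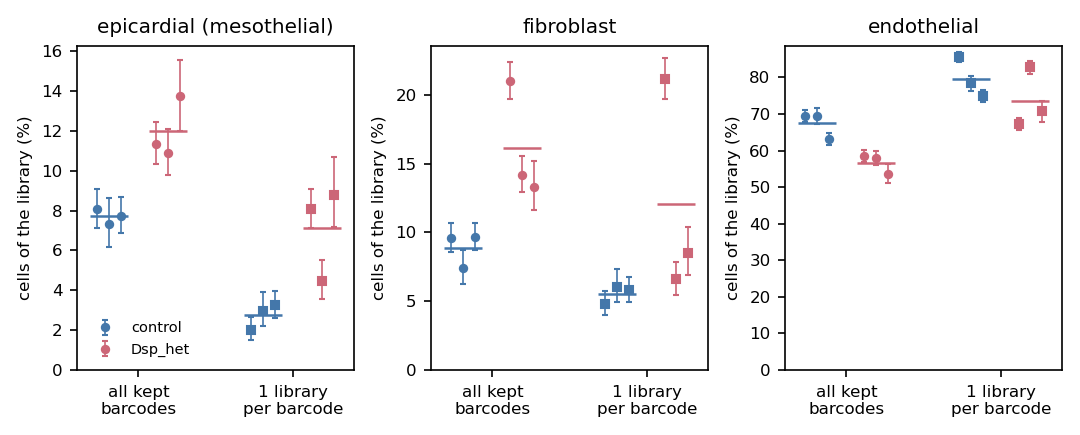
Percent of the cells of each library (vertical axes) in 3 classes, for all kept barcodes and for 1 library per barcode; points are libraries with 95% exact intervals, and horizontal lines are group means. All Dsp_het libraries lie above all control libraries for epicardial-like and fibroblast-like cells in both settings, while the endothelial-like groups overlap with 1 library per barcode.

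Summed over all kept cells, 5 of 13149 genes rose in Dsp_het and none fell (edgeR, adjusted p = 0.0446 for each; 1845 genes at an unadjusted p under 0.05). Lcn2 (chromosome 2, 32384633 to 32388252, minus strand), which encodes an iron-binding secreted protein, rose from 4.44 ± 0.980 to 15.6 ± 0.777 normalized CPM (mean ± SD, n = 3 each; log2 fold change 1.80, SE 0.19). Star (chromosome 8, 25806555 to 25815982, plus strand), which moves cholesterol into mitochondria, rose from 3.502 ± 0.329 to 11.5 ± 1.49 CPM (1.71, SE 0.19). Aldh1a2 (chromosome 9, 71215789 to 71296243, plus strand), the retinoic acid enzyme of the epicardium, rose from 21.24 ± 3.497 to 59.8 ± 8.58 CPM (1.48, SE 0.16). Bst1 (chromosome 5, 43818885 to 43843986, plus strand), a surface enzyme that cleaves NAD, rose from 29.6 ± 3.48 to 70.8 ± 8.22 CPM (1.26, SE 0.13). Sbsn (chromosome 7, 30751471 to 30756134, plus strand), which encodes the secreted epithelial protein suprabasin, rose from 15.6 ± 0.779 to 34.4 ± 2.18 CPM (1.14, SE 0.11). Star lies outside the naming rule by level and is named as 1 of the 5 smallest p-values. Within the epicardial-like class the same 5 genes had log2 fold changes between 0.07 and 0.63, none of which passed.

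The largest decreases by p-value were in Unc5b (log2 fold change -0.62, adjusted p = 0.0693) and Pcdh17 (-0.65), which encode a netrin receptor and a protocadherin, the actin bundler Fscn1 (-0.59), Trdc, the constant chain of the gamma-delta T cell receptor (-5.47, each adjusted p = 0.0736), and the transcription factor Prdm1 (-0.72, adjusted p = 0.0850), and they miss the threshold. Without Dsp_het library 2, Unc5b (0.0399), Pcdh17 (0.0407), Trdc (0.0480) and Prdm1 (0.0307) passed (8.75e-06 to 0.340 over the alternatives of the 4 genes). Pcdh17 and Fscn1 were among the 10 leading genes of an endothelial-like cluster led by Apln and Kit, with 840 control and 431 Dsp_het cells. Whether their decrease follows the number of those cells was not tested. The fibroblast genes Pdgfra (log2 fold change 1.08, SE 0.42) and Col1a1 (1.03, SE 0.37) were highest in Dsp_het library 1 and did not pass, with adjusted p = 0.303 and 0.265. Over the alternatives Pdgfra was 0.36 to 1.35 and Col1a1 0.51 to 1.37, and Col1a1 passed without Dsp_het library 2 (1.37, adjusted p = 0.0346; 0.0346 to 0.591 over the alternatives). The growth factors Tgfb1 (-0.37, adjusted p = 0.240), Fgf1 (0.44, adjusted p = 0.627) and Fgf2 (0.54, adjusted p = 0.353) did not pass. Nor did Postn (0.43), Acta2 (-0.29) and Pparg (-0.41). Postn was -0.24 without Dsp_het library 3, and Acta2 was 0.23 without control library 3.

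Of 35 lists tested over all cells, 18 passed with camera at its preset correlation, 12 upward and 6 downward, and none passed with an estimated correlation (lowest adjusted p = 0.453) or with fry (lowest adjusted p = 0.106). All 24 testable epicardial (mesothelial) markers were higher in Dsp_het, with a median log2 fold change of 1.30; 1 of them, Aldh1a2, passed over all genes and 24 passed adjusted over the list alone. Its camera adjusted p was 7.06e-29, and the adjusted p = 0.453 with an estimated correlation. The epithelial programme, of keratins, claudins and mesothelial genes, was higher in 18 of 18 members (median 1.29, 0 passed over all genes and 17 adjusted over the list alone). Of 48 fibroblast markers 45 were higher (median 0.97, 0 passed and 36 adjusted over the list alone), as were 33 of 37 genes of fibrillar collagen and extracellular matrix (median 0.89, 0 passed, 21 higher and 3 lower adjusted over the list alone). Of 49 paracrine growth factors 40 were higher (median 0.67, 0 passed, 15 higher and 2 lower adjusted over the list alone). For these 4 lists the adjusted p with an estimated correlation was 0.453, 0.453, 0.468 and 0.453. The endothelial markers were lower in 39 of 45 members (median -0.30, none adjusted over the list alone), the macrophage or monocyte markers in 30 of 31 (median -0.63, none) and the interferon response genes in 27 of 30 (median -0.27, none), with adjusted p = 0.471, 0.578 and 0.453 with an estimated correlation. The mix of cells moved with the epicardial and endothelial lists. Epicardial-like cells were 7.71% of control and 11.997% of Dsp_het cells, and endothelial-like cells 67.4% and 56.7%. The share of macrophage-like cells went against their markers, at 3.57% and 4.47%. The lists were tested on summed UMIs. Epicardial-like cells gave 494710, 395820 and 1165200 of 10715000, 7044300 and 15769000 UMIs in control. In Dsp_het they gave 2068200, 1018400 and 1652100 of 13908000, 9611000 and 9066800. Macrophage-like cells gave 541140, 365190 and 780680 UMIs in control and 84035, 277470 and 586690 in Dsp_het.

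Other lists that passed upward over all cells included epithelial-mesenchymal transition (19 of 21 higher), TGF-beta signalling (20 of 30), canonical WNT targets (9 of 10), YAP and TEAD targets (15 of 19), unfolded protein response (22 of 24) and dissociation and immediate early response (21 of 32). Downward they were cell cycle (20 of 29 lower), pericyte markers (17 of 20) and T or NK cell markers (12 of 12). The adjusted p with an estimated correlation was between 0.453 and 0.742 for these 9 lists, and adjusted over the list alone 3, 3, 5, 1, 0 and 0 members were higher, with 1 WNT target lower and none in the 3 downward lists. The pericyte call changed sign without control library 3 (adjusted p = 0.9504) and ended without control library 2 (0.0589) or Dsp_het library 1 or 2 (0.0930 and 0.531), and the dissociation call changed sign without control library 1 (0.952) and ended without Dsp_het library 1 or 3 (0.0977 and 0.0826). Other calls ended without control library 1 (YAP 0.0509, unfolded protein 0.0539, T or NK 0.0539), without control library 3 (T or NK 0.0664) or without Dsp_het library 1 (cell cycle 0.333, unfolded protein 0.264, T or NK 0.169). Lists that did not pass (lowest adjusted p = 0.0572) were desmosome and adherens junction, myofibroblast activation, adipogenesis and lipid handling, p53 targets and senescence, inflammatory cytokines and NF-kappaB targets, MHC class I and complement, nuclear and mitochondrially encoded oxidative phosphorylation, glycolysis and hypoxia, ribosomal proteins, sex-linked genes, and lymphatic endothelial, smooth muscle, B cell, cardiomyocyte, erythroid and cycling cell markers. Median, mean and test differed in sign for MHC class I and complement (-0.03, 0.30, upward), ribosomal proteins (-0.00163, 0.0148, upward), smooth muscle markers (0.09, -0.06, downward) and cardiomyocyte markers (0.33, 0.32, downward). Neutrophil, adipocyte and platelet markers had too few testable members.

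The calls of the 5 genes over all cells depended on the processing and on single libraries, while their log2 fold changes stayed positive in every alternative (Lcn2 1.69 to 2.34, Star 1.62 to 1.85, Aldh1a2 1.32 to 1.63, Bst1 1.04 to 1.46, Sbsn 1.02 to 1.29). No gene passed with all deposited barcodes, the stricter cell filter, equal numbers of cells or the replicate block. None passed without control library 1, 2 or 3 either, 1 other gene passed without Dsp_het library 3, and 17 and 330 genes passed without Dsp_het libraries 1 and 2. No gene passed with 1 library per barcode, where the 5 genes had adjusted p-values between 0.0918 and 0.131 (1.10e-10 to 0.315 over all alternatives); 465 genes passed with DESeq2, all 5 among them (on simulated data 17.3% of its calls were false, against 7.36% with edgeR), and 1 other gene passed with sex as a covariate.

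Within epicardial-like cells, the class in which Dsp was highest, the comparison asks whether these cells themselves changed. The deep and shallow cells of the class were 38 and 215, 42 and 91, and 85 and 185 in the control libraries, and 190 and 215, 73 and 233, and 89 and 115 in the Dsp_het libraries. No gene passed among 8740 (edgeR, 297 genes at an unadjusted p under 0.05; 0 with DESeq2). The smallest p-values among increases, all with an adjusted p of 1, were in Il3ra, the interleukin-3 receptor (log2 fold change 1.12, SE 0.26), Nov, a secreted matricellular protein (2.02, SE 0.48), the growth factor Bmp6 (1.33, SE 0.34), the securin Pttg1 (0.75) and the mitochondrial gene mt-Nd3 (0.73). Among decreases they were in the growth factor Gdf2 (-1.39, SE 0.36), Cnot2 (-0.77), the desaturase Scd2 (-0.72), the haem enzyme Alad (-0.64) and the transcription factor Ets2 (-0.67). Wt1 (0.17, SE 0.16), Tgfb1 (0.32, SE 0.37), Fgf1 (-0.85, SE 0.32), Fgf2 (-0.21), Pdgfra (0.08), Col1a1 (0.21, SE 0.19) and Acta2 (0.37) did not pass. Leaving out single libraries reversed Pdgfra (-0.64 without control library 3, -0.22 without Dsp_het library 1), Col1a1 (-0.08 without Dsp_het library 3), Tgfb1 (-0.00496 without Dsp_het library 1) and Acta2 (-0.87 without Dsp_het library 1, -0.14 without control library 3).

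In epicardial-like cells, 4 of 30 lists passed with the preset correlation, and none with an estimated correlation (lowest adjusted p = 0.829) or fry. Dissociation and immediate early response genes, induced by handling and stress, were higher in 23 of 30 members (median 0.25, 0 passed over all genes and 4 adjusted over the list alone), as were mitochondrially encoded oxidative phosphorylation genes in 11 of 13 (median 0.19, 0 passed and 1 adjusted over the list alone). Endothelial markers were lower in 23 of 28 members (median -0.29) and genes of adipogenesis and lipid handling in 16 of 22 (median -0.18), with none adjusted over the list alone. Each of the 4 had an adjusted p = 0.829 with an estimated correlation. The epicardial (mesothelial) markers (17 of 24 higher, median 0.09) and the epithelial programme (13 of 18 higher, median 0.09) did not pass (adjusted p = 0.118 for both, and 0.921 for the epicardial markers with an estimated correlation), although both passed with 1 library per barcode at the preset correlation (0.0440 for each). The dissociation call ended without Dsp_het library 3 (adjusted p = 0.477), the oxidative phosphorylation call without Dsp_het library 2 (0.239), the endothelial call without control library 3 or Dsp_het library 3 (0.916 and 0.477), and the adipogenesis call without control library 1 or 3 (0.0972 and 0.0837). The number of lists was 10 without Dsp_het library 1, 7 without control library 2 or Dsp_het library 2, and 8 with 1 library per barcode; 1 gene passed without control library 3 and 2 without Dsp_het library 1, mt-Nd3 among the latter (0.96, adjusted p = 0.0102; 0.00107 to 1.00 over the alternatives).

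Within fibroblast-like cells, which ask the same question for the matrix-producing class, Cilp rose in Dsp_het. Cilp (chromosome 9, 65265180 to 65280605, plus strand) encodes cartilage intermediate layer protein, a secreted matrix protein that binds TGF-beta1. Its level went from 29.99 ± 1.61 to 82.2 ± 10.5 normalized CPM (mean ± SD, n = 3 each; log2 fold change 1.46, SE 0.17; edgeR adjusted p = 0.00886). No other gene of 8779 passed (268 at an unadjusted p under 0.05), and it is a member of both the myofibroblast and the fibroblast list. The next smallest p-values, which miss the threshold, belonged to the matrix protease Mmp3 (1.58, SE 0.31, adjusted p = 0.709), the peptidase Dpp4 (0.81), Stbd1 (1.605) and Igfbp6 (0.57), and to decreases of Rnaset2b (-1.38), Wdfy1 (-1.47), the cardiac troponin Tnni3 (-1.30), the haemoglobin gene Hbb-bs (-1.12) and Tctn1 (-0.81). Col1a1 (-0.05, SE 0.16), Postn (-0.47, SE 0.37), Pdgfra (0.14, SE 0.18), Tgfb1 (0.45, SE 0.36), Fgf2 (0.17) and Wt1 (0.99, SE 0.36) did not pass. Pdgfra was -0.07 without control library 3 and Col1a1 was 0.12 without Dsp_het library 2.

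**Figure D4:**
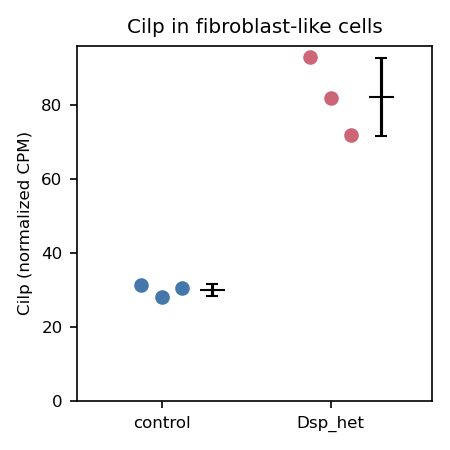
Normalized CPM of Cilp (vertical axis) in the fibroblast-like cells of each library; points are the 3 control and 3 Dsp_het libraries, with the group mean and SD. The control libraries lie between 28.2 and 31.3 and the Dsp_het libraries between 71.9 and 92.9.

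In fibroblast-like cells, 11 of 27 lists passed with the preset correlation, 9 upward and 2 downward, and none with an estimated correlation (lowest adjusted p = 0.269) or fry. Inflammatory cytokines and NF-kappaB targets were higher in 18 of 21 members (median 0.49, camera adjusted p = 2.30e-06; adjusted p = 0.269 with an estimated correlation), none of them over all genes or adjusted over the list alone. Dissociation and immediate early response genes were higher in 26 of 32 (median 0.23, 0 passed and 4 adjusted over the list alone; adjusted p = 0.332 with an estimated correlation). MHC class I and complement genes were higher in 18 of 21 (median 0.20) and endothelial markers lower in 24 of 30 (median -0.62), with adjusted p = 0.388 and 0.417 with an estimated correlation and none adjusted over the list alone. The other lists that passed were unfolded protein response (19 of 23 higher), YAP and TEAD targets (13 of 14), paracrine growth factors (27 of 38), TGF-beta signalling (22 of 30), mitochondrially encoded oxidative phosphorylation (10 of 13), epicardial markers (4 of 5) and, downward, nuclear oxidative phosphorylation (30 of 38 lower), with adjusted p between 0.332 and 0.701 with an estimated correlation and none adjusted over the list alone. The myofibroblast list (6 of 10 higher, 1 passed over all genes and 1 adjusted over the list alone, adjusted p = 0.125) and the collagen and extracellular matrix list (16 of 35 higher, median -0.02, mean 0.03, downward, adjusted p = 0.980) did not pass. Of the calls, the inflammatory and dissociation calls stood with each library left out. Without control library 3 the calls of endothelial markers (adjusted p = 0.885), MHC class I (0.0540), TGF-beta (0.301), epicardial markers (0.301) and mitochondrial and nuclear oxidative phosphorylation (0.0738 and 0.668) ended. Without Dsp_het library 1 those of endothelial markers (0.0902), MHC class I (0.0946), unfolded protein (0.235), YAP (0.213), paracrine factors (0.533), epicardial markers (0.235) and mitochondrial oxidative phosphorylation (0.0677) ended. Single calls also ended without control library 1 (unfolded protein 0.0976, mitochondrial 0.275, epicardial 0.0533), control library 2 (TGF-beta 0.0785, epicardial 0.0985), Dsp_het library 2 (epicardial 0.0693, mitochondrial 0.0693, nuclear 0.0889) and Dsp_het library 3 (mitochondrial 0.111, nuclear 0.953), and the epicardial call also with 1 library per barcode (0.0617).

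The fibroblast-like cells came mainly from a deep cluster with a median of 7667 UMIs and a shallow cluster of which 96.1% were copies, in proportions that differed between libraries. The deep and shallow cells were 113 and 187, 86 and 47, and 156 and 178 in the control libraries, and 551 and 135, 110 and 285, and 88 and 110 in the Dsp_het libraries. Cilp also passed with 1 library per barcode, at a log2 fold change of 1.70, and with DESeq2. It missed the threshold without control library 1, 2 or 3 (adjusted p = 0.0796, 0.122 and 0.101), without Dsp_het library 1 or 2 (0.0803 and 0.0515) and with equal numbers of cells (0.895; 3.30e-10 to 0.895 over all alternatives). Without Dsp_het library 3, 5 genes passed, Rnaset2b among them (-1.89, adjusted p = 0.0322; 2.67e-09 to 1.00 over the alternatives). The number of lists was 5 without control library 3 and 5 without Dsp_het library 1.

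Within endothelial-like cells no gene passed among 11313 (edgeR, 538 genes at an unadjusted p under 0.05; 14 with DESeq2). The smallest p-values among increases were in Prss23, a secreted protease (log2 fold change 1.16, SE 0.16), Ltc4s, leukotriene C4 synthase (0.84, SE 0.12), and C3, the central complement component (1.31, SE 0.19), each with an adjusted p of 0.0697. Islr2 (1.73, SE 0.29, adjusted p = 0.190) and Itih5 (1.35, SE 0.24, adjusted p = 0.236) followed. Among decreases they were in Wdfy1 (-1.24, SE 0.22, adjusted p = 0.236), the Notch-regulated gene Nrarp (-0.44), Hlx (-0.46), the necroptosis kinase Ripk3 (-0.51) and Tbc1d9 (-0.64). Wt1 (0.00891, SE 0.14), Tgfb1 (-0.11), Fgf2 (-0.07), Pdgfra (0.06), Col1a1 (0.35), Postn (-0.25) and Pparg (-0.12) did not pass. Of these, Wt1 was -0.11 without control library 3 and -0.09 without Dsp_het library 1, Fgf2 was 0.17 without control library 2 and 0.09 without Dsp_het library 2, and Pdgfra was -0.16 without control library 1 and -0.12 without Dsp_het library 1. Col1a1 was -0.01 without Dsp_het library 1, and Postn was 0.27 without Dsp_het library 1 and 0.22 without control library 3. Without Dsp_het library 2, 10 genes passed, Prss23, C3, Ltc4s and Itih5 among them (adjusted p = 0.0174, 0.0151, 0.0335 and 0.00844; 1.08e-14 to 0.937 over the alternatives of the 4 genes), and 2 genes passed without control library 2. The makeup of the class was not tested. Endothelial-like cells numbered 2178, 1263 and 2210 in the control and 2086, 1626 and 797 in the Dsp_het libraries. Of these the venous cluster held 326, 136 and 251 in control and 389, 331 and 229 in Dsp_het. That was a larger part in every Dsp_het library than in any control library, and 12.3% of the cluster were copies. The parts overlapped for the cluster led by Apln and Kit (366, 149 and 325 against 247, 93 and 91). They also overlapped for the interferon cluster (196, 164 and 192 against 224, 116 and 58) and that with Hspa1a and Egr1 (78, 144 and 215 against 50, 165 and 22). All kept cells numbered 3134, 1817 and 3494 in control and 3566, 2806 and 1486 in Dsp_het. Of these, the cluster led by Apln and Kit was a smaller part in every Dsp_het library than in any control library.

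In endothelial-like cells, 10 of 32 lists passed with the preset correlation, 6 upward and 4 downward, and none with an estimated correlation or fry. The epithelial programme was higher in 7 of 7 members (median 0.84, 0 passed and 3 adjusted over the list alone; camera adjusted p = 2.27e-07, adjusted p = 0.127 with an estimated correlation) and the epicardial markers in 8 of 8 (median 0.70, 0 passed and 2 adjusted over the list alone; adjusted p = 0.134 with an estimated correlation). Both are markers of the epicardial-like class, whose share was higher in Dsp_het. Cardiomyocyte markers were lower in 18 of 19 members (median -1.09, none adjusted over the list alone; adjusted p = 0.639 with an estimated correlation), and interferon response genes in 25 of 30 (median -0.13, none; adjusted p = 0.633). The other lists that passed were fibroblast markers (26 of 37 higher), paracrine growth factors (21 of 29), TGF-beta signalling (22 of 29), MHC class I and complement (14 of 22) and, downward, nuclear oxidative phosphorylation (35 of 38 lower) and the dissociation response (22 of 31), with adjusted p between 0.458 and 0.701 with an estimated correlation. Adjusted over the list alone, 2 fibroblast markers and 2 MHC class I or complement genes were higher. The cardiomyocyte call ended without control library 3 (adjusted p = 0.592) or Dsp_het library 1 (0.228), and the fibroblast marker call without Dsp_het library 1 (0.0618). Calls of TGF-beta, MHC class I, nuclear oxidative phosphorylation and the dissociation response ended without control library 3 (0.123, 0.715, 0.2503 and 0.857) and without Dsp_het library 3 (0.0636, 0.716, 0.347 and 0.347). TGF-beta (0.150), MHC class I (0.199) and dissociation (0.150) also ended without Dsp_het library 1, dissociation without control library 2 (0.568), and 17 lists passed without Dsp_het library 2.

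Within pericyte-like cells, the contractile cells around capillaries, 9 genes rose and 5 fell among 3342 (edgeR, 301 at an unadjusted p under 0.05). Cxcl9 (chromosome 5, 92321347 to 92328079, minus strand), a chemokine induced by interferon-gamma, rose from 43.0 ± 35.6 to 318 ± 337 normalized CPM (mean ± SD, n = 3 each; log2 fold change 2.73, SE 0.40, adjusted p = 2.34e-05). Rsad2 (chromosome 12, 26442746 to 26456452, minus strand), the antiviral protein viperin, rose from 197 ± 77.7 to 427 ± 122 CPM (1.33, SE 0.23, adjusted p = 0.000527). The interferon-induced genes Isg20 (1.92, SE 0.41), Ifit2 (1.62, SE 0.32), Ifi44 (1.59, SE 0.33), Gbp2 (1.31, SE 0.28) and Ifi27l2a (1.40, SE 0.28) also rose, Ifi27l2a with overlapping groups, as did the phospholipase Plcb1 (1.30, SE 0.28) and the carbonic anhydrase Car4 (0.95, SE 0.22). Cyr61, a matricellular target of YAP (-1.01, SE 0.25), the mitochondrial gene mt-Nd4l (-0.89, SE 0.19), Rsrp1 (-0.77, SE 0.18) and the heat shock gene Hspa1a (-1.14, SE 0.29, with overlapping groups) fell. The last decrease, Gm8797 (-1.25, SE 0.27), lies outside the naming rule and was named after its values were seen. Tgfb1 (0.55), Postn (0.44), Acta2 (-0.38) and Pparg (0.26) did not pass.

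The interferon response list was higher in 22 of 24 members in pericyte-like cells (median 0.73, 5 passed over all genes and 15 adjusted over the list alone), with a camera adjusted p of 6.37e-15 and an adjusted p = 0.651 with an estimated correlation. Downward lists were mitochondrially encoded oxidative phosphorylation (13 of 13 lower, median -0.17, 1 passed and 3 adjusted over the list alone), nuclear oxidative phosphorylation (28 of 38, median -0.15, none) and the dissociation response (16 of 23, median -0.15, 1 passed and 1 adjusted over the list alone), with adjusted p = 0.829, 0.651 and 0.829 with an estimated correlation. These 4 of 21 lists were all that passed, and the dissociation call ended without control library 2 or 3 (adjusted p = 0.134 and 0.711) or Dsp_het library 3 (0.702). The class was small, with 56, 59 and 144 control and 38, 47 and 47 Dsp_het cells, and 38.9% of its cells were copies. No gene passed with DESeq2, without Dsp_het library 3, or with 1 library per barcode and at least 10 cells. The number was 4 without control library 3, 21 without control library 1, 22 without Dsp_het library 2 and 2 with all deposited barcodes. Cxcl9 passed in every alternative that tested it except DESeq2 (adjusted p = 4.17e-16 to 1.00), but was not tested without Dsp_het library 3 or with 1 library per barcode, and Rsad2 missed the threshold in both (0.110 and 0.232; 1.46e-05 to 0.232). Ifi27l2a was 0.573 without Dsp_het library 3, Hspa1a -1.80 without Dsp_het library 3, and Ifi44 0.93 without control library 3, and none of these passed. Calls also ended without control library 1 (Cyr61, -0.84), control library 2 (Isg20 1.76, Car4 0.89, Cyr61 -0.91, Rsrp1 -0.73, Hspa1a -0.97, Gm8797 -0.94), Dsp_het library 1 (Gbp2 0.99, Cyr61 -0.97, Rsrp1 -0.77) and Dsp_het library 2 (Car4 0.86, Cyr61 -0.87, Rsrp1 -0.79, Hspa1a -0.86, Gm8797 -1.21).

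Within macrophage-like cells no gene passed among 5248 (edgeR, 324 at an unadjusted p under 0.05; 0 with DESeq2). The class joined a shallow cluster, 97.7% of it copies, with 170 control and 263 Dsp_het cells to a deep cluster with 141 and 55. In Dsp_het library 1 only 2 of 101 cells remained without copies, with 5234 of 84035 UMIs. The smallest p-values were in Ifi202b, an interferon-induced DNA sensor (log2 fold change -3.17, SE 0.56, adjusted p = 0.0834), and in Eng, an endothelial TGF-beta coreceptor (1.25, SE 0.27, adjusted p = 0.401). With an adjusted p of 0.497 there followed the chemokine Ccl3 (1.11), Epas1 (1.48), Arcn1 (1.35), Nr4a1 (1.16), Ifi27l2a (-0.65), Epb41l4aos (-1.48) and Pnrc1 (-0.72), and then Rps29 (-0.65, adjusted p = 0.517). Tgfb1 was -0.11. Ifi202b passed without control library 1, 2 or 3 (adjusted p = 0.0145, 0.000741 and 0.0172) and without Dsp_het library 2 (0.00968; 9.57e-12 to 1.00 over the alternatives). Its log2 fold change was -4.81 without Dsp_het library 2 and -4.81 to -2.19 over the alternatives, from 58, 11 and 81 UMIs in the control and 0, 7 and 2 in the Dsp_het libraries. The number of genes that passed was 2, 5, 19 and 3 in these fits, with Eng among them without control library 3 (1.46, adjusted p = 0.0250; 0.00365 to 1.00 over the alternatives). Of 22 lists 7 passed with the preset correlation, and none with an estimated correlation or fry. Endothelial markers were higher in 29 of 30 members (median 0.52, 0 passed and 3 adjusted over the list alone), and macrophage or monocyte markers were lower in 24 of 29 (median -0.14, none), with adjusted p = 0.517 and 0.497 with an estimated correlation. Ribosomal proteins (28 of 39 lower), nuclear oxidative phosphorylation (28 of 38 lower), the dissociation response (20 of 29 higher), adipogenesis and lipid handling (10 of 14 higher) and p53 targets (8 of 11 higher) were the others, with adjusted p between 0.517 and 0.520 with an estimated correlation. Adjusted over the list alone, 6, 0, 3, 2 and 1 of their members passed. Without control library 1 the dissociation call changed sign (adjusted p = 0.924) and the adipogenesis call ended (0.358), and without Dsp_het library 2 both ended (0.0643 for each). The p53 call ended without control library 2 (0.115), control library 3 (0.811) and Dsp_het library 1, 2 or 3 (0.209, 0.0643 and 0.174).

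Within cycling cells no gene passed among 2983 (edgeR, 104 at an unadjusted p under 0.05; 0 with DESeq2), and none of 20 lists passed. The smallest p-values were in the kinesin Cenpe (log2 fold change 1.83, SE 0.33, adjusted p = 0.274), the taurine transporter Slc6a6 (2.15, SE 0.42, adjusted p = 0.340) and Trdc (-5.19, SE 0.91, adjusted p = 0.274). After them came Cstb (1.43), Sppl2a (1.03), Aspm (1.18), Fen1 (-1.70), Tk1 (-1.08), Ssrp1 (-1.04) and Tipin (-1.50). Tgfb1 was -0.23. Of the cell cycle list 18 of 29 members were lower (median -0.32, adjusted p = 0.0516). The number of lists was 3 and 5 without control libraries 1 and 2, and 4, 8 and 1 without Dsp_het libraries 1, 2 and 3.

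Whether the genotype effect differed between classes was tested directly. Between epicardial-like and endothelial-like cells, the effect differed for 5 of 11987 genes (edgeR, 634 at an unadjusted p under 0.05), all with the lower effect in epicardial-like cells. They were Spock2, a secreted proteoglycan, Cd74, the invariant chain of MHC class II, Upk3b, a uroplakin of mesothelium, C3 and the growth factor Igf1, with differences in log2 fold change between -1.02 and -2.01. Upk3b leads the deep epicardial-like cluster, and 8 of 8 epicardial markers were higher in endothelial-like cells (median 0.70). No gene passed between fibroblast-like and endothelial-like cells (0 of 12234, edgeR; 538 at an unadjusted p under 0.05), where the matrix gene Ccdc80 came closest (-1.30, SE 0.21, adjusted p = 0.0756). None passed between epicardial-like and fibroblast-like cells either (0 of 9914, edgeR; 376 at an unadjusted p under 0.05). Between epicardial-like and endothelial-like cells no gene passed without control library 1 or 2, and 13 passed without Dsp_het library 2. Between fibroblast-like and endothelial-like cells 15, 2, 9 and 4 genes passed without control libraries 1 and 3 and Dsp_het libraries 2 and 3, and 1 gene passed between epicardial-like and fibroblast-like cells without control library 3.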

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

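The tests on pericyte-like cells and on other splits of the libraries, the alternative with 1 library per barcode, and the deciding quantity of the Xist test (a Poisson limit in place of a plain ratio) were chosen after the results were seen.

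The genotype effect differed between epicardial-like and endothelial-like cells for 5 genes, by an interaction test in edgeR. Spock2 differed by a log2 of -1.44 (SE 0.20, adjusted p = 0.00867), from 1.31 in endothelial-like to -0.16 in epicardial-like cells; it missed the threshold without control library 1 or 2 (0.0578 and 0.131; 1.47e-09 to 0.131 over its alternatives). Cd74 differed by -1.51 (SE 0.23, adjusted p = 0.0144), from 1.03 to -0.53, and missed it without control library 1, 2 or 3 (0.0578, 0.180 and 0.0769; 6.41e-13 to 0.180). Upk3b differed by -2.01 (SE 0.32, adjusted p = 0.0144), from 2.03 to -0.02, and missed it without control library 1 or 2 (0.0578 and 0.180; 3.71e-08 to 0.180). C3 differed by -1.40 (SE 0.23, adjusted p = 0.0179), from 1.31 to -0.20, and missed it without control library 1, control library 2 or Dsp_het library 1 (0.0852, 0.186 and 0.0581) or with 1 library per barcode (-1.44, 0.0613; 7.11e-14 to 0.186). Igf1 differed by -1.02 (SE 0.18, adjusted p = 0.0420), from 0.68 to -0.27, and missed it without any 1 library (0.0529 without Dsp_het library 2 to 0.304 without control library 3; 0.000469 to 0.304). Of the 5 genes only Spock2 passed with the stricter cell filter, and Igf1 also missed the threshold with doublet calls kept and with Leiden resolution 0.5. Of the 10 splits of the 6 libraries, 3 gave at least as many genes for this difference, and the highest other split gave 16. The 10 splits cannot give a share under 0.05, and a split with 16 genes points to a structure of the samples, whose nature was not tested. Epicardial markers were higher in 8 of 8 members in endothelial-like cells (median 0.70), and the difference of Upk3b, a leading gene of the epicardial-like class, lies in its endothelial-like value; RNA of epicardial-like cells in that class was not tested.

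Barcodes in several libraries stood out in data that the comparisons do not use as a measurement: 5092 occurrences were copies of a barcode with more UMIs elsewhere. Chance reuse of barcodes is argued against by the profiles, since a copy was closer to its own owner than to another owner of the same class by a median Spearman correlation of 0.120 (SD 0.0140 over libraries). Molecules assigned to the wrong library remain open and go with the values: Xist in male libraries was at least 2152 times higher, by exact Poisson limits, in copies with an owner in a female library than in barcodes found in 1 library. A candidate explanation is index exchange between libraries sequenced together, which was not itself tested. Ambient RNA of the droplet run, which would not follow the owner of a barcode, is argued against for Xist. In male libraries, copies with an owner in a male library held 0 Xist UMIs among 1376118. Those with an owner in a female library held 333 among 653238. No biological explanation was tested.

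The genes called over all cells included Aldh1a2, a mesothelial marker, and all 24 testable mesothelial markers were higher. A change of these genes inside epicardial-like cells, as the whole cause, is argued against: their median log2 fold change there was 0.178 times that over all cells (spread 0.161). The mesothelial markers passed inside the class with 1 library per barcode (camera adjusted p = 0.0440), and with all kept barcodes they did not (0.118, 0.921 with an estimated correlation and 1.00 with fry), so a change of part of them is left open. The other alternatives were not followed for this list inside the class. A larger share of epicardial-like cells remains open, since the median inside the class was 0.264 (SE 0.238) against 1.48 over all cells, and the pattern may follow the mix of cells. The mix itself can differ by genotype or by the yield of the sort for EGFP-positive non-myocytes, which the design does not part.

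The interferon-induced genes called in pericyte-like cells were weighed against copies and endothelial RNA, and both stay open. Without copies, 5 of the 9 genes called as higher could be tested (Isg20, Rsad2, Gbp2, Plcb1 and Car4, median log2 fold change 1.41, SE 0.323, each adjusted p at least 0.232), and Cxcl9, Ifit2, Ifi44 and Ifi27l2a could not. The 40 endothelial markers had a median log2 fold change of 0.131 (SE 0.192), but in control they already stood at a median of 0.734 times their level in endothelial-like cells, which would hide a further share. Car4 leads capillary clusters and Ifit2, Ifi44 and Rsad2 lead the interferon cluster of endothelial-like cells, which goes with endothelial RNA. Against it, 25 of 30 interferon response genes were lower in Dsp_het endothelial-like cells (median -0.13, adjusted p = 0.633 with an estimated correlation). The size of the interferon cluster decides nothing here, since its part of the endothelial-like cells overlapped between groups. It held 196 of 2178, 164 of 1263 and 192 of 2210 in control, and 224 of 2086, 116 of 1626 and 58 of 797 in Dsp_het. An effect of genotype stays open as a hypothesis, as do differences between single animals such as infection, which were not tested.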

How the results depend on the processing

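The alternatives with 1 library per barcode (at 20 or at 10 cells) and without the highest doublet scores were chosen after the data were seen. Where no cause is given for a change below, the cause was not tested.

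Of 1884 values of named genes under an alternative, 1591 kept direction and side of the threshold, 182 fell short of it, 76 passed it newly and 35 reversed. Of 583 values of lists 397 kept both, 183 fell short and 3 reversed. Of 98 values of shares 90 kept both, 3 passed newly and 5 reversed. Of 240 counts 147 stayed within 1.5 times.

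Over all cells, 5 genes passed. With no filter on low counts 203 passed, with DESeq2 465 and with sex as a covariate 1. None passed (edgeR) with all deposited barcodes (1859 at an unadjusted p under 0.05), the stricter cell filter (1680), equal numbers of cells (1351), the replicate block or 1 library per barcode, where DESeq2 on the main cells gave 465. Leaving out 1 library gave 0 to 330 genes, with 0 without control libraries 1, 2 and 3 and 330 without Dsp_het library 2. Fits that leave out a library have fewer samples. Dsp over all cells was -0.0108 with the block and -0.56 to 0.29 with a library left out.

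In epicardial-like cells 42 genes passed with no filter and 0 to 2 with a library left out. In fibroblast-like cells the counts were 74 with no filter, 2 with all barcodes, 2 with doublet calls kept, 0 with equal numbers of cells (fewer cells), 5 with the block, 2 with sex and 0 to 5 with a library left out. In endothelial-like cells they were 188 with no filter, 1 with equal numbers, 14 with DESeq2, 5 with the block, 5 with sex and 0 to 10 with a library left out. In pericyte-like cells they were 28 with no filter, 2 with all barcodes, 3 with equal numbers, 0 with DESeq2, 4 with sex, 0 with 1 library per barcode at 10 cells and 0 to 22 with a library left out. In macrophage-like cells they were 40 with no filter, 7 with sex and 0 to 19 with a library left out, and in cycling cells 32 with no filter and 1 with the block.

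For the difference between fibroblast-like and endothelial-like cells, 69 genes passed with no filter, 4 with all barcodes, 5 with doublet calls kept and 0 to 15 with a library left out. Between epicardial-like and endothelial-like cells 77 passed with no filter, 1 with the stricter filter, 10 without the highest doublet scores and 0 to 13 with a library left out. Between epicardial-like and fibroblast-like cells 22 passed with no filter and 0 to 1 with a library left out.

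With an estimated correlation 0 lists passed, and with fry 0, over all cells and in epicardial-like, fibroblast-like, endothelial-like, pericyte-like and macrophage-like cells. In epicardial-like cells 8 lists passed with 1 library per barcode and 4 to 10 with a library left out. The range with a library left out was 5 to 14 in fibroblast-like, 7 to 17 in endothelial-like and 0 to 8 in cycling cells, where the block gave 4. The dissociation list reversed over all cells (p 0.00123 to 0.952 with a library left out) and in macrophage-like cells (3.14e-06 to 0.880), and the pericyte markers over all cells (1.14e-07 to 0.9504).

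EdgeR on cell counts gave log2 ratios of 0.63 for epicardial-like, 0.86 for fibroblast-like and -0.25 for endothelial-like cells, past a threshold that the exact test cannot reach with 3 against 3 libraries. The share of cycling cells was -0.0439 with all barcodes, -0.22 with 1 library per barcode and -0.13 to 0.34 with a library left out. That of macrophage-like cells was -0.0528 with the stricter filter and -0.43 with 1 library per barcode.

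Genes that reversed had passed no test. Pdgfra in epicardial-like cells was -0.0264 with the stricter filter, -0.14 with DESeq2, -0.0136 with the block, -0.22 with sex, -0.0156 without the highest doublet scores and -0.64 to 0.76 with a library left out. Col1a1 there was -0.0691 with equal numbers and -0.0827 to 0.39 with a library left out, Tgfb1 -0.0049647 to 0.50 and Acta2 -0.87 to 1.45. In fibroblast-like cells Fgf2 was -0.20 with equal numbers, and with a library left out Pdgfra was -0.0717 to 0.27 and Col1a1 -0.17 to 0.12. In endothelial-like cells Wt1 was -0.0044901 with no filter, -0.0240 with all barcodes, -0.0345 with the stricter filter and -0.11 to 0.0907 with a library left out. Fgf2 there was 0.0509 with the stricter filter and -0.28 to 0.17 with a library left out, and Pdgfra -0.10 with the stricter filter, -0.16 with equal numbers and -0.16 to 0.22. Col1a1 there was -0.0142 to 0.63 and Postn -1.30 to 0.27 with a library left out. Over all cells Postn was -0.24 to 0.77 and Acta2 -0.62 to 0.23.

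No sign of a pairing by replicate number was seen: deviations from the group mean correlated at 0.034, -0.056 and -0.066 between libraries of the same number, and the highest of all pairs was 0.133. Sums over all cells also carry the mix of cells and the sex of each library, so a shared day, litter or run cannot be excluded. Pericyte-like, macrophage-like and cycling cells gave no value with 1 library per barcode at 20 cells, cycling cells none with the stricter filter, and Dsp in epicardial-like cells none with equal numbers. Depth limits Dsp, with 15 to 37 UMIs per library in kept barcodes.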

Other observations

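The tests on other splits of the 6 libraries into 3 and 3, and the Y-linked genes in copies, were chosen after the results were seen, while the edgeR and DESeq2 counts of the real groups were planned.

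The 10 splits cannot give a share under 0.05. For genes, the real split and the highest other gave 5 and 0 over all cells (1 of 10 splits as large), 0 and 11 in epicardial-like cells (10), 1 and 4 in fibroblast-like cells (4), 0 and 0 in endothelial-like cells (10), 14 and 10 in pericyte-like cells (1), 0 and 12 in macrophage-like cells (10) and 0 and 1 in cycling cells (10). The real counts of 0 stand beside 297, 538, 324 and 104 genes at an unadjusted p under 0.05 with edgeR in epicardial-like, endothelial-like, macrophage-like and cycling cells, and DESeq2 called 0, 14, 0 and 0. For lists, the same numbers were 18 and 25 over all cells (5 of 10 as large), 4 and 11 in epicardial-like cells (9), 11 and 12 in fibroblast-like cells (2), 10 and 14 in endothelial-like cells (6), 4 and 7 in pericyte-like cells (7), 7 and 12 in macrophage-like cells (7) and 0 and 8 in cycling cells (10). For differences of the genotype effect they were 0 and 8 between fibroblast-like and endothelial-like cells (10), and 0 and 21 between epicardial-like and fibroblast-like cells (10). Splits that call 11 genes in epicardial-like cells, 4 in fibroblast-like cells, 12 in macrophage-like cells and 21 between classes, where the real split calls at most 1, point to a structure of the samples, whose nature was not tested.

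In female libraries, Y-linked genes were 150.14 CPM (186 UMIs) in copies with an owner in a male library and 0.104 CPM in barcodes found in 1 library. Copies with an owner in the other female library held no UMI of these genes among 222756.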
